A study of Mus musculus with 12 samples.

How the data were processed

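Gene expression was measured in cultured mouse fibro/adipogenic progenitors (FAPs) on 12 Affymetrix Mouse Gene 1.0 ST arrays, 2 for each of 6 groups. The groups combine 3 antisense oligonucleotides (AMOs) with 2 doses of the growth factor PDGF-AA, which the labels give as 0 and 50 uM. Per the labels' protocols, cells grew for 2.5 days, were transfected with 10 µM AMO for 48 hours, and were transfected again with 10 µM AMO, with or without PDGF-AA, for another 48 hours. Biotinylated cDNA was made from 100 ng of total RNA, and each biological replicate pools cells of 2 mice, per the labels and the series' design text.

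The deposited values are log2 expression values made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version of either. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of each transcript cluster. Array medians lay between 6.04 and 6.23 on the log2 scale, with no sign of further centring. No scanner files were used here, so the background correction and the summary over probes stand as the authors made them. The number of arrays limits the precision.

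The table holds 35556 transcript clusters. The platform annotation gives exactly 1 gene symbol to 21789 of them, which stand for 19939 genes. It gives several symbols to 1621 and does not list 12146, which are unnamed here and were tested only as an alternative. Gene identifiers were matched to RefSeq gene names of the assembly GRCm38.p6, where 21698 of the 21789 were found and 0 symbols changed. That assembly was used for names only.

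Groups were compared with limma 3.58.1 in R 4.3.3. A means model of the 6 groups was fitted to all 12 arrays, so that every comparison shares an estimate of the spread with 6 residual degrees of freedom. Empirical Bayes moderation used neither an intensity trend nor robust fitting, and p-values were adjusted by Benjamini-Hochberg over the 21789 clusters, with a threshold of 0.05. The comparisons were the PDGF-AA effect averaged over AMOs and within each AMO, each pair of AMOs averaged over PDGF-AA and at each dose, and the 3 differences between PDGF-AA effects. Log2 changes are given with the standard error of this model. This design, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined, except where the text says otherwise.

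Replicate numbers 1 and 2 recur in every group, and no label says what they share. The deviations of same-numbered arrays from their group means correlated in all 15 pairs of groups, at 0.20 to 0.61 across clusters, above the criterion of 0.1 set beforehand. All 12 arrays correlated best with an array of their own replicate number, and 0 with the other array of their group. By this criterion, a hint from the data and not from the labels, the numbers pair the samples. A fit with the replicate number as a fixed block (5 residual degrees of freedom) is given beside a result where it changes a call. The block leaves log2 changes as they are and alters their errors.

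For each comparison 24 gene lists were tested. They cover PDGF ligands and receptors, immediate early genes, cell cycle, fibrillar collagens, other matrix genes, myofibroblast genes, matrix proteases, adipocyte differentiation, FAP and fibroblast markers, cholesterol synthesis, glycolysis, interferon response, p53 targets, the unfolded protein response, inflammatory cytokines, complement, TGF-beta and BMP targets, and growth factors. A further 6 lists hold markers of other cells: myogenic, endothelial, macrophage and leukocyte, smooth muscle and pericyte, tendon, and Schwann cells. Camera in limma was run with its preset inter-gene correlation of 0.01 and adjusted over the 24 lists, and a gene with several clusters entered by its brightest. Two-sided alternatives were camera with a correlation estimated for each list and fry. Fry tests whether the members of a list move one way and does not compare them with other genes. Sizes are given as the median log2 change of the members.

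The genes named are Pdgfra and the other PDGF genes, the 3 genes with the smallest p where none passed, and members at the ends of each list described. Genes that passed only with the replicate block are named as well, a choice made after their values were seen. Symbols of predicted or unnamed genes, small RNAs and olfactory receptors are not named.

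A further planned test took the 100 genes with the smallest p for PDGF-AA with control AMO, since fewer than 20 passed, and asked by fry whether they moved in the same direction more with pA AMO than with 5'ss AMO, with p adjusted over 3 contrasts. Alternatives were a filter on dim clusters (mean log2 above 5.516, the 40 percent mark), all 35556 clusters, repeated quantile normalization, median centring, trend and robust moderation, array weights, smaller sets of arrays in the fit, a fold minimum of 1.5, and leaving out each array in turn. Cyclic loess between arrays, and response genes chosen again with the block or without single control AMO arrays, were added after seeing the data. So were the scaling and dim-cluster alternatives for list shifts, and every alternative for counts with the block. List shifts and named genes without single arrays come from fits without the block, so their values can also take in the difference between the replicates.

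The procedure was tested on simulated data of 21789 genes with 100 genes changed at each fold. The simulated arrays carried the replicate difference and the residual spread that the block fit gave in these data. A gain from the block was thus built in and says nothing on whether the block is right. For the averaged PDGF-AA effect it recovered 77 of 100 genes changed 1.5-fold and 96 of 100 changed 2-fold, and 92 and 97 with the block. For PDGF-AA with control AMO alone it recovered 23 and 66, and 55 and 90 with the block. Unchanged genes called in these 2 comparisons were 1 and 2, and 6 and 8 with the block. List tests were simulated on the averaged PDGF-AA effect and counted at an unadjusted p under 0.05, while lists in the report were called by adjusted p. Camera with the preset correlation called 2.29% of 480 unchanged lists when genes were independent and 32.5% when members shared a correlation of 0.2. With the estimated correlation these shares were 0.833% and 4.17%.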

Results

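FAPs are mesenchymal cells of skeletal muscle that express the PDGF receptor PDGFRα and can form fibroblasts and adipocytes. They were isolated from uninjured hindlimb muscle of male C57Bl/6 mice and treated in culture. The title of the series concerns intronic polyadenylation of PDGFRα transcripts and muscle fibrosis. The pA AMO targets the intronic polyadenylation site of Pdgfra, the 5'ss AMO targets a 5' splice site named in the labels as intronic, and a control AMO serves as the reference. Each AMO was given without PDGF-AA, a ligand of PDGFRα, and with a dose of it that the labels give as 50 uM, high for a growth factor and not checked here, with 2 arrays in each of the 6 groups. Values on the 12 arrays ran from 1.36 to 14.10 on the log2 scale.

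Pdgfra (transcript cluster 10522503) was among the brightest genes and lay within a narrow range in all 12 arrays, from 12.72 to 12.92. Its group means were 12.75 with control AMO, 12.76 with pA AMO and 12.91 with 5'ss AMO without PDGF-AA, and 12.77, 12.78 and 12.86 with PDGF-AA (largest SD 0.058, n = 2 each). With 5'ss AMO it was higher than with control AMO in all 4 arrays of each, by 0.13 (SE 0.062), which did not pass (adjusted p = 0.995, and 0.354 with the replicate block). The cluster's value does not separate full-length from truncated Pdgfra transcripts, so it does not check the action of the pA and 5'ss AMOs. The averaged PDGF-AA change was -0.0050 for Pdgfra, 0.069 for Pdgfrb, -0.12 for Pdgfa, 0.024 for Pdgfb, -0.16 for Pdgfc, 0.22 for Pdgfd and -0.25 for Pdgfrl, and none passed.

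The first comparison asks what PDGF-AA changed in FAPs on average over the 3 AMOs. Igf1, which encodes insulin-like growth factor 1, was lower with PDGF-AA, at -0.60 (SE 0.077, 6 arrays against 6). Comp, a cartilage and tendon matrix protein, was at -0.88 (SE 0.169), the small collagen-binding proteoglycan Fmod by -0.53 (SE 0.081), and the calcification inhibitor Mgp by -0.42 (SE 0.061). Car9, a carbonic anhydrase induced by hypoxia, was higher by 0.52 (SE 0.089), and the lactate exporter Slc16a3 by 0.38 (SE 0.060). Of these 6 genes only Mgp had no overlap between the arrays with and without PDGF-AA. An average need not hold in each AMO: with 5'ss AMO Fmod was at -0.032, while Igf1 was at -0.557. In limma 0 of 21789 clusters passed, with a smallest adjusted p of 0.294 (Igf1) and 738 clusters at an unadjusted p under 0.05. With no change at all, a share of 0.05 of the clusters would be expected there, which is more than 738. Of such counts without the block, here and below, only the 1308 for 5'ss against control AMO with PDGF-AA exceeded that share. Counts below it give no sign of changed genes. With the replicate block 21 passed, of which 6 rose and 15 fell. These include the 6 genes just named, with adjusted p of 0.041 for Comp and 0.0481 for the other 5. Others that fell with the block were Egfl6 (-0.83), C7 (-0.55), Slc5a3 (-0.50), the Wnt antagonist Sfrp1 (-0.49), Olfml2b (-0.43), Kng1 (-0.42), Gfra1 (-0.41), Gas6 (-0.36), Mmp23 (-0.35) and Samd5 (-0.35). Sparcl1 (0.37), Nt5c1b (0.35), Galnt16 (0.33) and Htr2a (0.31) rose with the block. Kng1 and Kng2 are near-identical paralogs, so probes of either are uncertain. The count of 21 fell to 0 or 1 without any single array but 5'ss AMO with PDGF-AA replicate 2, without which it was 24, of which 11 are among the 21.

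**Figure D1:**
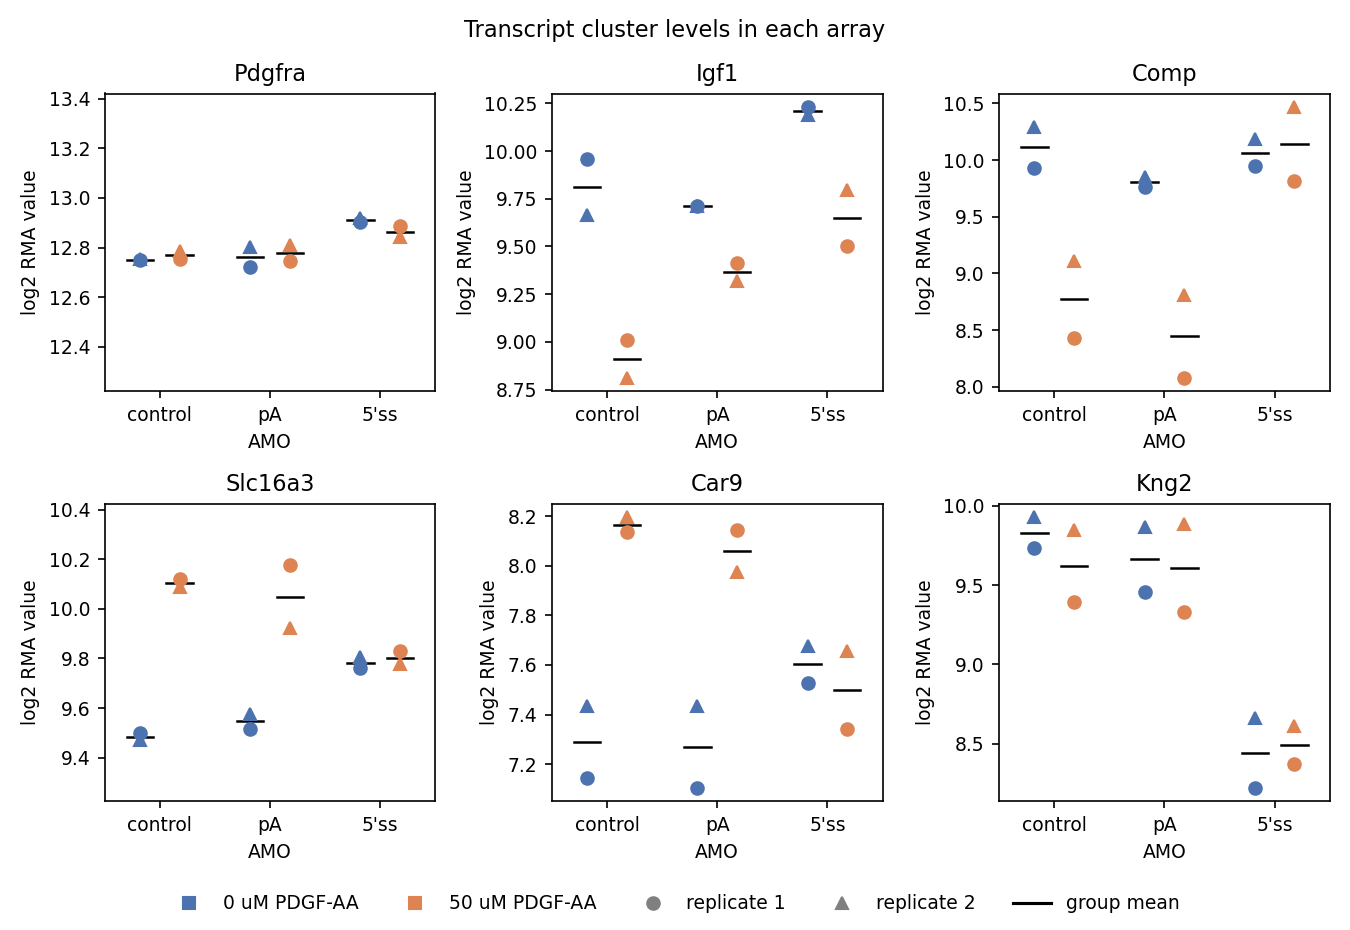
Log2 RMA values of 6 transcript clusters in each of the 12 arrays, by AMO, with colour for the PDGF-AA dose, symbols for the replicate number and bars for group means. Pdgfra lies between 12.72 and 12.92 in all arrays, and Kng2 is lower in the 4 arrays with 5'ss AMO than in the other 8.

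The glycolysis and glucose uptake list rose with PDGF-AA averaged over AMOs. Its median change was 0.22, with 16 of 17 genes above 0, such as the glycolytic enzyme Aldoc at 0.37 (SE 0.075). Camera gave an adjusted p of 1.07e-22 with the preset correlation, with adjusted p = 0.072 with an estimated correlation and 0.010 by fry. Of its members 13 rose adjusted over the list alone and 0 over all genes, where Slc16a3 passed only with the replicate block (adjusted p = 0.0481 in limma). The growth factor list fell (median -0.079, 15 of 20 below 0, adjusted p = 9.89e-06, with adjusted p = 0.072 with an estimated correlation). Adjusted over the list alone 3 of its members fell, among them Igf1 and Igfbp3, an IGF-binding protein at -0.51 (SE 0.111). The median was -0.051 without 5'ss AMO without PDGF-AA replicate 2 and -0.046 without pA AMO with PDGF-AA replicate 1.

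Of the 9 tendon genes 7 were lower with averaged PDGF-AA and the list fell (adjusted p = 0.00314, with adjusted p = 0.104 with an estimated correlation). Its median was close to 0 at -0.010 because Comp and Fmod carried the shift, and 2 members fell adjusted over the list alone. Without 5'ss AMO without PDGF-AA replicate 1 the median was 0.037 and the call was lost, and without each of the other 11 arrays the median lay further below 0, down to -0.13. Complement genes also fell (median -0.070, 10 of 12 below 0, adjusted p = 0.0031, with adjusted p = 0.389 with an estimated correlation), with C2 at -0.27 (SE 0.063). That call was lost without pA AMO without PDGF-AA replicate 2 and without control AMO with PDGF-AA replicate 1 (medians -0.085 and -0.040). Cholesterol synthesis (0.068) and the interferon response (0.17) also rose, and other matrix genes (-0.043), myofibroblast genes (-0.068), FAP markers (-0.069), inflammatory cytokines (-0.056) and TGF-beta targets (-0.063) also fell with the preset correlation. For these 7 lists the adjusted p with an estimated correlation lay between 0.34 and 0.723, and each lost its call without at least 1 array. The other 13 lists did not pass. Their medians were -0.0050 for PDGF genes, -0.010 for immediate early genes, 0.020 for cell cycle, 0.014 for collagens, 0.028 for proteases, 0.026 for adipocyte genes, -0.0060 for p53 targets, -0.016 for the unfolded protein response, -0.021 for myogenic, 0.046 for endothelial, 0.0050 for macrophage, -0.0020 for smooth muscle and 0.013 for Schwann cell genes.

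**Figure D2:**
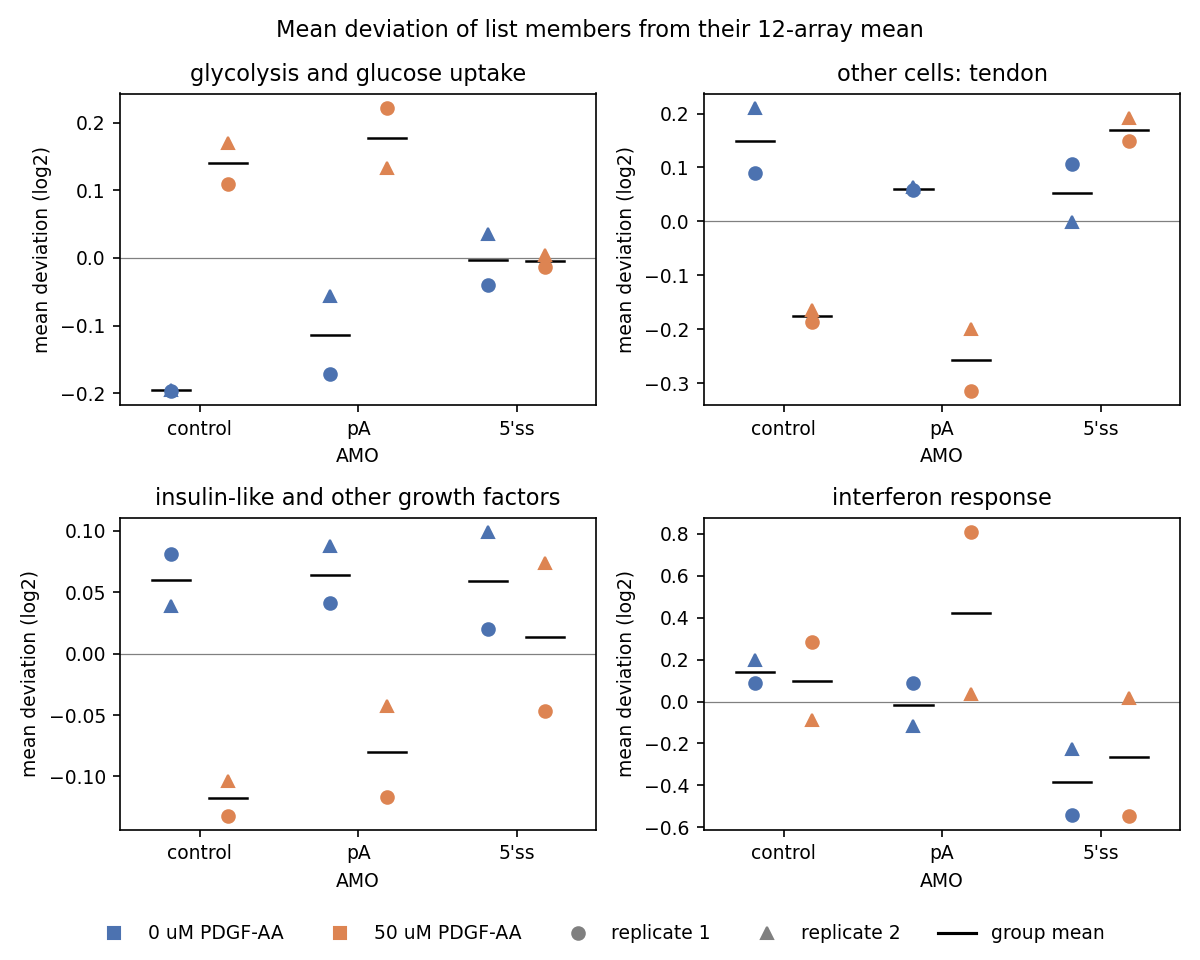
Mean deviation of the members of 4 gene lists from their 12-array mean, in log2 units, for each array by AMO, with colour for the PDGF-AA dose, symbols for the replicate number and bars for group means. The interferon score is highest in pA AMO with PDGF-AA replicate 1, at 0.81, and lowest in 5'ss AMO with PDGF-AA replicate 1, at -0.54.

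With control AMO alone, PDGF-AA was compared in 2 arrays against 2. Igf1 was lower by a log2 change of -0.90 (SE 0.134) and Samd5 by -0.64 (SE 0.099), while Egln3, a prolyl hydroxylase of the hypoxia response, was higher by 0.85 (SE 0.14). No cluster passed in limma (smallest adjusted p 0.467), and 1049 had an unadjusted p under 0.05. The block also gave 0, with a smallest adjusted p of 0.0704. The glycolysis list rose, with a median of 0.35 and 16 of 17 genes above 0, including Aldoc at 0.72 (SE 0.13) and Slc16a3 at 0.62 (SE 0.103). Its adjusted p was 8.76e-16, with adjusted p = 0.0875 with an estimated correlation and 0.0127 by fry, and 13 members rose adjusted over the list alone. Tendon genes fell (median -0.24, 8 of 9 below 0, adjusted p = 0.000557, with adjusted p = 0.0875 with an estimated correlation), with Comp at -1.34 (SE 0.293) and Fmod at -0.71 (SE 0.14). The tendon median was -0.40 and -0.10 without control AMO without PDGF-AA replicate 1 and replicate 2. Growth factors fell (median -0.072, 13 of 20 below 0, adjusted p = 0.000557, with adjusted p = 0.123 with an estimated correlation), with Igfbp3 at -0.94 (SE 0.192). The growth factor median was -0.13 without control AMO without PDGF-AA replicate 2 and -0.11 without control AMO with PDGF-AA replicate 2. With the preset correlation 2 lists rose and 7 fell with control AMO, and 0 passed with an estimated one (smallest adjusted p 0.0875). The others among them were cholesterol synthesis (0.12), other matrix (-0.063), myofibroblast (-0.073), FAP marker (-0.093), inflammatory (-0.094) and complement genes (-0.16), and all but other matrix genes lost their call without at least 1 array.

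With pA AMO, the change with PDGF-AA was -0.84 for Fmod (SE 0.14), -0.62 for the cornified envelope gene Sprr1a (SE 0.109) and 0.79 for Car9 (SE 0.155), in 2 arrays against 2. In limma 0 clusters passed (smallest adjusted p 1.0, 517 at an unadjusted p under 0.05), and 0 with the block (0.164). The glycolysis list rose (median 0.28, 16 of 17 above 0, adjusted p = 1.09e-21, with adjusted p = 0.0688 with an estimated correlation and 0.025 by fry). The glucose-phosphorylating enzyme Hk2 was at 0.56 (SE 0.149) and Aldoc at 0.55 (SE 0.13), and 9 members rose adjusted over the list alone. Tendon genes fell (median -0.15, 6 of 9 below 0, adjusted p = 0.0004, with adjusted p = 0.0688 with an estimated correlation), with Comp at -1.36 (SE 0.293). Growth factors fell (median -0.12, 16 of 20 below 0, adjusted p = 0.000126, with adjusted p = 0.0765 with an estimated correlation), with Gas6 at -0.51 (SE 0.125). Without pA AMO with PDGF-AA replicate 2 these medians were -0.28 and -0.19.

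Cholesterol synthesis genes also rose with PDGF-AA under pA AMO, all 20 of them above 0 (median 0.23, adjusted p = 1.66e-10, with adjusted p = 0.417 with an estimated correlation). Lss was at 0.42 (SE 0.126) and Idi1 at 0.37 (SE 0.195), both enzymes of the pathway. The interferon list rose (median 0.33, 23 of 26 above 0, adjusted p = 3.98e-11, with adjusted p = 0.417 with an estimated correlation), with the antiviral genes Mx1 at 1.60 (SE 0.495) and Ifit2 at 1.33 (SE 0.397). Myogenic genes fell (median -0.35, 22 of 22 below 0, adjusted p = 7.24e-07, with adjusted p = 0.417 with an estimated correlation), with the fusion factor Mymk at -0.69 (SE 0.307) and the acetylcholine receptor subunit Chrna1 at -0.60 (SE 0.313). The cholesterol and interferon shifts lean on replicate 1. In replicates 1 and 2 the interferon score went from 0.089 to 0.807 and from -0.118 to 0.036. Among myogenic genes Mymk was at -0.935 and -0.444, and Chrna1 at -0.754 and -0.44. Tnnt1 and Pax7, with the smallest falls, rose in replicate 2 (0.041 and 0.202). Medians without single arrays come from fits without the block, so they also take in the difference between the replicates. Without pA AMO with PDGF-AA replicate 1 the cholesterol median was 0.086 and the interferon median 0.0030, which ended the interferon call. The interferon median was 0.21 without pA AMO without PDGF-AA replicate 2 and 0.62 without pA AMO with PDGF-AA replicate 2. The myogenic call was lost without pA AMO without PDGF-AA replicate 1 (-0.059), and its median was -0.59 without replicate 2 of that group and -0.22 without pA AMO with PDGF-AA replicate 2. In total 6 lists rose and 5 fell with pA AMO with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.0688). Those not given above were cell cycle (0.11), collagens (0.079), proteases (0.044), inflammatory (-0.049) and complement genes (-0.12), and each lost its call without at least 1 array.

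With 5'ss AMO, the glycolysis list did not pass (median 0.021, 10 of 17 above 0, adjusted p = 0.939). The 3 genes with the smallest p were Kcnj14, a potassium channel, at -0.65 (SE 0.133), Rnase2b at 0.56 (SE 0.119) and Btnl5-ps at 0.51 (SE 0.119), in 2 arrays against 2. Limma passed 0 clusters (smallest adjusted p 1.0, 358 at an unadjusted p under 0.05), and 0 with the block (0.626). Adipocyte genes rose with PDGF-AA (median 0.21, 24 of 28 above 0, adjusted p = 2.99e-06, with adjusted p = 0.688 with an estimated correlation), with the adipokine Adipoq at 1.48 (SE 0.97) and the fatty acid transporter Cd36 at 1.42 (SE 1.082). The list's score rose in replicate 1 only, from -0.249 to 0.554, and in replicate 2 it went from 0.176 to 0.11. Within replicates 1 and 2 Adipoq was at 3.293 and -0.342, and Cd36 at 3.144 and -0.3. Cell cycle genes fell (median -0.11, 40 of 46 below 0, adjusted p = 1.29e-05, with adjusted p = 0.688 with an estimated correlation), with Kif11 at -0.26 (SE 0.183). Cholesterol synthesis genes fell (median -0.14, 19 of 20 below 0, adjusted p = 6.49e-05, with adjusted p = 0.688 with an estimated correlation), with Lss at -0.34 (SE 0.126). Without 5'ss AMO with PDGF-AA replicate 1 these medians were 0.13, 0.033 and 0.047 and all 3 calls were lost, and without replicate 2 of that group the cell cycle and cholesterol medians were -0.26 and -0.29. The adipocyte median was 0.073, with its call lost, without 5'ss AMO without PDGF-AA replicate 1 and 0.37 without replicate 2. Myogenic genes, markers of another cell type, rose alongside (median 0.18, 19 of 22 above 0, adjusted p = 0.00691, with adjusted p = 0.732 with an estimated correlation). Their call was lost without replicate 1 of 5'ss AMO without PDGF-AA (-0.0060) and with PDGF-AA (-0.0070), and their median was 0.34 and 0.36 without replicate 2 of each. Collagens (-0.072) and myofibroblast genes (-0.12) fell, and lost their calls without replicate 1 of 5'ss AMO without PDGF-AA (-0.052 and -0.053) and with PDGF-AA (-0.044 and -0.027). In all 2 lists rose and 4 fell with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.688). Tendon genes passed with the block (adjusted p = 0.0409) and not without it (0.092).

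**Figure D3:**
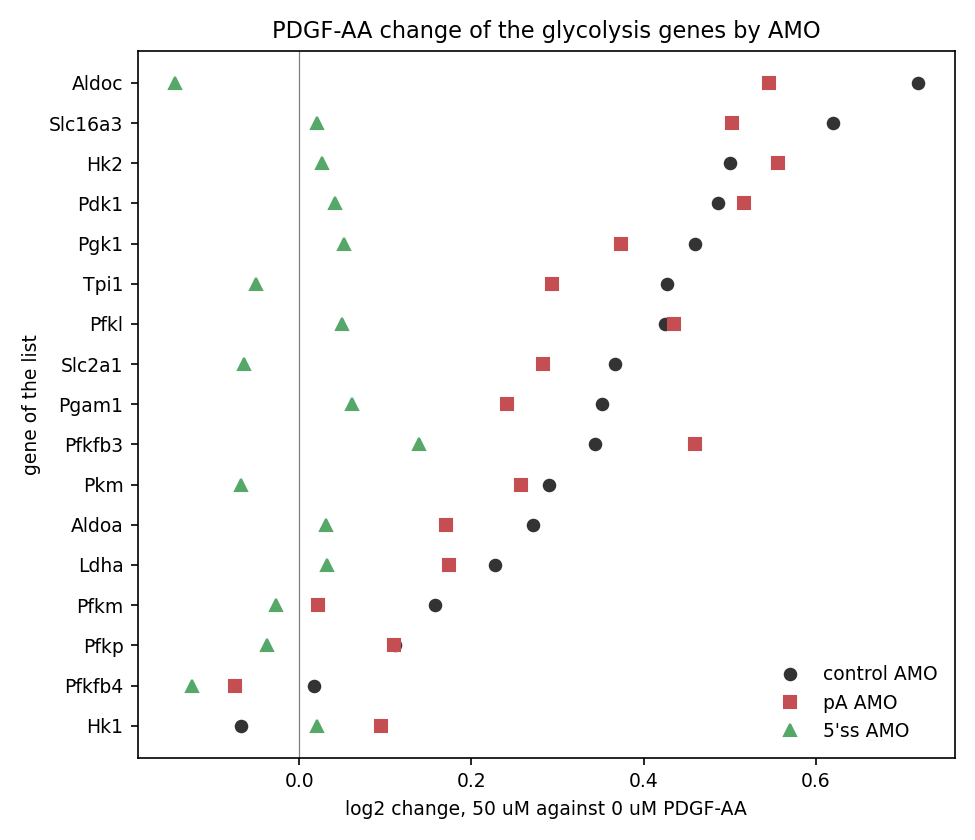
Log2 change of the 17 glycolysis and glucose uptake genes, 50 against 0 uM PDGF-AA, with a symbol per AMO. The list's median change is 0.35 with control AMO, 0.28 with pA AMO and 0.021 with 5'ss AMO.

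The PDGF-AA effects of the AMOs were next compared with each other. The glycolysis list responded less with 5'ss AMO than with control AMO, by a median of -0.36 (16 of 17 below 0, adjusted p = 2.3e-12, with adjusted p = 0.151 with an estimated correlation). Fry gave 0.0375, and 0.0601 with the block. Aldoc differed by -0.86 (SE 0.184) and Slc16a3 by -0.60 (SE 0.146), and 3 members fell adjusted over the list alone. Part of this difference was a higher level with 5'ss AMO before PDGF-AA. In replicates 1 and 2 the list's score without PDGF-AA was -0.04 and 0.035 with 5'ss AMO, and -0.197 and -0.195 with control AMO. With PDGF-AA it was -0.013 and 0.004 against 0.109 and 0.17. Against 5'ss AMO, the response with pA AMO was higher by a median of 0.32 in 17 of 17 genes (adjusted p = 3.99e-13, with adjusted p = 0.105 with an estimated correlation), with Aldoc at 0.69 and Hk2 at 0.53. Between pA and control AMO the glycolysis list did not pass. Tendon genes ran the other way: their PDGF-AA effect with 5'ss AMO exceeded that with control AMO by 0.32 in 9 of 9 genes (adjusted p = 1.51e-05, with adjusted p = 0.0616 with an estimated correlation), with Comp at 1.42 (SE 0.414) and the cornea and tendon proteoglycan Kera at 0.77 (SE 0.332). That median was 0.48 without control AMO without PDGF-AA replicate 1.

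Cholesterol synthesis genes responded more with pA than with 5'ss AMO, in 20 of 20 genes (median 0.37, adjusted p = 3.99e-13, with adjusted p = 0.339 with an estimated correlation), with Idi1 at 0.53. The median was 0.24 without pA AMO with PDGF-AA replicate 1 and 0.17 without 5'ss AMO with PDGF-AA replicate 1. Part of this difference was a lower level with pA AMO before PDGF-AA. In replicates 1 and 2 the score without PDGF-AA was -0.157 and -0.126 with pA AMO, and 0.083 and 0.117 with 5'ss AMO. With PDGF-AA it was 0.179 and -0.056 against -0.187 and 0.117. The mean difference was 0.606 in replicate 1 and 0.07 in replicate 2. No single gene passed: limma gave 0 clusters for each of these 3 differences, with and without the block. Clusters at an unadjusted p under 0.05 numbered 564 for pA minus control, 643 for 5'ss minus control and 418 for pA minus 5'ss. The smallest p belonged to Stmn2 (0.87), Fbxo48 (0.78) and Mrgpra6 (-0.87), to Teddm3 (-0.82), Smim9 (0.71) and Fbxo48 (0.81), and to Rpe65 (-0.63), the steroid dehydrogenase Hsd3b6 (2.27) and Lss (0.76), in that order of differences.

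The 100 genes with the smallest p for PDGF-AA with control AMO, of which 57 were higher and 43 lower, were then followed in the other arrays. In the direction set by control AMO, their median change was 0.26 with pA AMO, with 80 of 100 in that direction (fry in limma, adjusted p = 0.0022 over the 3 contrasts given here). With 5'ss AMO it was 0.039, with 63 of 100 (adjusted p = 0.292), and the difference between the AMOs was 0.23, with 78 of 100 genes above 0 (adjusted p = 0.017). The control AMO value of 0.53 is inflated by the choice. The difference depended on how the genes were chosen. Chosen above the dim threshold it was 0.29, chosen with the block 0.18, and chosen with both 0.27, and these 3 passed by fry before adjustment. It was 0.072 for the 500 genes with the smallest p, and 0.092, 0.092, 0.12 and 0.036 when the genes were chosen again without control AMO without PDGF-AA replicate 1, its replicate 2, control AMO with PDGF-AA replicate 1 and its replicate 2, and none of these 5 values passed.

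The pA AMO was compared with control AMO for the effect of masking the intronic polyadenylation site. Hmcn1, a large extracellular matrix protein, was higher with pA AMO, by 0.79 (SE 0.136) and 0.73 (SE 0.133) in its 2 clusters with the smallest p, in 4 arrays against 4. All 77 clusters of Hmcn1 were above 0, with a median of 0.38, and all 77 were above 0 with 5'ss AMO as well, with a median of 0.18. Both comparisons share the control arrays, from which part of this common direction can come. Mrgpra6, a sensory neuron receptor gene with a low signal, was at -0.53 (SE 0.095). Among single clusters 0 passed in limma (smallest adjusted p 0.898, 708 at an unadjusted p under 0.05), and 0 with the block (0.281). Cell cycle genes were higher as a list (median 0.074, 40 of 46 above 0, adjusted p = 3.03e-08, with adjusted p = 0.683 with an estimated correlation), with the mitotic genes Hmmr at 0.37 (SE 0.122) and Tpx2 at 0.26 (SE 0.109). That median was 0.15 without control AMO without PDGF-AA replicate 1 and 0.021 without its replicate 2. Other matrix genes (0.0225) and smooth muscle genes (0.0488) passed, and with the block their adjusted p was 0.0802 and 0.0747. With these, 7 lists were higher and 0 lower with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.27). The remaining 4 were proteases (0.074), glycolysis (0.042), p53 targets (0.074) and myogenic genes (0.18), and of the 7 only the cell cycle list kept its call without each array in turn.

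Without PDGF-AA, the genes with the smallest p between pA and control AMO were Bex4 (-0.51), Slc35f2 (0.58) and the protease inhibitor Mug2 (0.49), with 2 arrays against 2. Limma gave 0 clusters (smallest adjusted p 1.0, 325 at an unadjusted p under 0.05), and 0 with the block. Myogenic genes were higher with pA AMO (median 0.42, 20 of 22 above 0, adjusted p = 2.16e-08, with adjusted p = 0.95 with an estimated correlation), with the sarcomere genes Actc1 at 0.66 (SE 0.456) and Myh3 at 0.64 (SE 0.561). This shift moved when single arrays were left out. Those fits had no block, so their medians also take in the difference between replicates 2 and 1, at -0.278 for myogenic genes. The median was -0.036 and 0.098 without control AMO without PDGF-AA replicate 2 and pA AMO without PDGF-AA replicate 1, which ended the call, and 0.83 and 0.65 without the other array of each group. The p53 list passed without the block (adjusted p = 0.0467) and not with it (0.116). Together 4 lists were higher and 2 lower with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.95). Beside the lists above they were cell cycle (0.053), glycolysis (0.068), cholesterol synthesis (-0.069) and interferon genes (-0.17), and each of the 6 lost its call without at least 1 array.

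With PDGF-AA, Mrgpra6 was at -0.97 (SE 0.134), Tnfsf18, a TNF family ligand, at 0.85 (SE 0.133), and Hmcn1 at 0.68 (SE 0.112) for pA against control AMO. Limma gave 0 clusters (smallest adjusted p 0.577, 1065 at an unadjusted p under 0.05), and 0 with the block (0.0613). Cell cycle genes were higher (median 0.099, 38 of 46 above 0, adjusted p = 3.11e-06, with adjusted p = 0.69 with an estimated correlation), and the median was 0.062 without pA AMO with PDGF-AA replicate 1. Interferon genes were higher (median 0.16, 20 of 26 above 0, adjusted p = 7.5e-05, with adjusted p = 0.702 with an estimated correlation), with Mx1 at 1.65 (SE 0.495) and Rsad2 at 1.35 (SE 0.529). The interferon median was -0.14 and 0.0090 without pA AMO with PDGF-AA replicate 1 and control AMO with PDGF-AA replicate 2, which ended the call, and 0.51 and 0.34 without the other array of each group. After cyclic loess it was 0.12 and no longer passed. Among lists 5 were higher and 1 lower with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.215). The 4 not yet given were other matrix genes (0.082), proteases (0.090), p53 targets (0.080) and macrophage genes (-0.13), of which the last 3 lost their call without at least 1 array.

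The 5'ss AMO was compared with control AMO for the effect of masking the 5' splice site. Kng2, a kininogen gene, was lower with 5'ss AMO by -1.26 (SE 0.166), in all 4 arrays against all 4. Arxes2, a gene linked to adipocyte differentiation, was higher by 0.78 (SE 0.092), and Tgfbi, a matrix protein induced by TGF-beta, by 0.56 (SE 0.074). The chemokine Ccl5 was at -0.80 (SE 0.106). Of all clusters 0 passed in limma (smallest adjusted p 0.0988, 1046 at an unadjusted p under 0.05). With the block 3 passed: Kng2 fell (adjusted p = 0.000287), and Arxes2 (0.0417) and Tgfbi (0.028) rose. The count with the block was 1 or 2 without each of 11 arrays and 10 without 5'ss AMO with PDGF-AA replicate 2, of which 2 are among the 3. Interferon genes fell as a list, 26 of 26 below 0 (median -0.41, adjusted p = 7.77e-19, with adjusted p = 0.448 with an estimated correlation), with Irf7, a transcription factor of the interferon response, at -0.93 (SE 0.217) and Ifit3 at -0.68 (SE 0.291). Adjusted over the list alone 7 members fell. The median lay between -0.29 and -0.55 without each array in turn. The fall was larger in replicate 1. There the scores without and with PDGF-AA were -0.542 and -0.544 with 5'ss AMO, and 0.086 and 0.282 with control AMO. In replicate 2 they were -0.228 and 0.019 against 0.199 and -0.086, so with PDGF-AA the sign was reversed. With the preset correlation 9 lists were higher and 2 lower, and 0 passed with an estimated one (smallest adjusted p 0.448). Higher with 5'ss AMO were other matrix (0.017), myofibroblast (0.040), adipocyte (0.13), FAP marker (0.028), unfolded protein response (0.041), inflammatory (0.0090), TGF-beta (0.066), growth factor (0.038) and tendon genes (0.049), and cell cycle genes (-0.078) were lower. Each of these 10 lost its call without at least 1 array.

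Without PDGF-AA, Kng2 was lower with 5'ss AMO by -1.39 (SE 0.234), and it alone passed with the block (adjusted p = 0.00266). Ect2l was at -0.77 and Ccl5 at -0.72. In limma 0 clusters passed (smallest adjusted p 1.0, 450 at an unadjusted p under 0.05), and the block count was 0 without control AMO without PDGF-AA replicate 1 and without either array of 5'ss AMO without PDGF-AA. Interferon genes fell, 26 of 26 below 0 (median -0.50, adjusted p = 4.21e-24, with adjusted p = 0.497 with an estimated correlation), with Irf7 at -0.98 (SE 0.307). Glycolysis genes were higher with 5'ss AMO before any PDGF-AA (median 0.18, 16 of 17 above 0, adjusted p = 9.39e-12, with adjusted p = 0.355 with an estimated correlation), with Aldoc at 0.48 (SE 0.13) and Hk2 at 0.46 (SE 0.149). That median was 0.11 without 5'ss AMO without PDGF-AA replicate 2. Cholesterol synthesis genes were also higher (median 0.18, 17 of 20 above 0, adjusted p = 2.36e-06, with adjusted p = 0.635 with an estimated correlation), with Tm7sf2 at 0.33 and Idi1 at 0.32. The TGF-beta list passed without the block (adjusted p = 0.0321) and not with it (0.0892). In this comparison 4 lists were higher and 2 lower with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.355). The unfolded protein response (0.067) and complement lists (-0.14) complete them, and these 2 and the TGF-beta list lost their call without at least 1 array.

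With PDGF-AA, Comp was higher with 5'ss than with control AMO by 1.37 (SE 0.293), Arxes2 by 1.21 (SE 0.131), Samd5 by 0.79 (SE 0.099) and Tgfbi by 0.79 (SE 0.105), and Kng2 was at -1.13 (SE 0.234), in 2 arrays against 2. In limma 0 clusters passed (smallest adjusted p 0.0601 for Arxes2, 1308 at an unadjusted p under 0.05). With the block 22 passed, 15 up and 7 down, with adjusted p of 0.0166 for Kng2, 0.0196 for Arxes2 and Tgfbi, 0.0205 for Samd5, and 0.0255 for Comp and Hacd2. Others that rose with the block were the axon guidance gene Draxin (1.10), Atp13a3 (0.99), Tspan18 (0.92), Fbxo48 (0.68), Stmn2 (0.68), Dennd4a (0.64), Plcb1 (0.63), angiotensinogen Agt (0.62), Cwf19l2 (0.61) and Fchsd2 (0.55). Mrgpra6 (-0.83), Cyp2d22 (-0.61), Galnt16 (-0.59) and the prostaglandin receptor Ptgdr2 (-0.57) fell with the block. The count with the block was 21 without 5'ss AMO with PDGF-AA replicate 2, of which 4 are among the 22, and was 4 or 5 without each of the pA AMO arrays and each control AMO array without PDGF-AA, and 0 without each of the other 5 arrays.

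Among the lists in the PDGF-AA arrays, tendon genes were higher with 5'ss than with control AMO, 9 of 9 above 0 (median 0.18, adjusted p = 0.000146, with adjusted p = 0.111 with an estimated correlation and 0.0284 by fry), with Fmod at 0.68 (SE 0.14). Growth factors were higher (median 0.073, 15 of 20 above 0, adjusted p = 0.000748, with adjusted p = 0.239 with an estimated correlation), with Igf1 at 0.74 (SE 0.134) and Igfbp3 at 0.63 (SE 0.192). That median was 0.14 and 0.042 without 5'ss AMO with PDGF-AA replicate 1 and replicate 2. Adipocyte genes were higher (median 0.22, 21 of 28 above 0, adjusted p = 4.25e-05, with adjusted p = 0.434 with an estimated correlation), with Cd36 at 2.01 (SE 1.082) and the fatty acid binding protein Fabp4 at 1.81 (SE 0.961). Their score was higher in replicate 1 only, at 0.554 with 5'ss AMO and -0.423 with control AMO, against 0.11 and 0.207 in replicate 2. The adipocyte call was lost without control AMO with PDGF-AA replicate 1 (0.12) and 5'ss AMO with PDGF-AA replicate 1 (0.13), and the median was 0.42 and 0.39 without replicate 2 of each. Glycolysis genes were lower (median -0.16, 15 of 17 below 0, adjusted p = 0.000748, with adjusted p = 0.434 with an estimated correlation), with Aldoc at -0.39 (SE 0.13) and Tpi1 at -0.35 (SE 0.098), and the call was lost without control AMO with PDGF-AA replicate 2 (-0.13). Interferon genes were lower (median -0.34, 24 of 26 below 0, adjusted p = 5.37e-06, with adjusted p = 0.559 with an estimated correlation), and this leaned on replicate 1. In replicate 2 the list's score was 0.019 with 5'ss AMO and -0.086 with control AMO. The interferon median was -0.10, with the call lost, without 5'ss AMO with PDGF-AA replicate 1, -0.18 without control AMO with PDGF-AA replicate 1, and -0.61 without 5'ss AMO with PDGF-AA replicate 2. The p53 list passed only with the block (adjusted p = 0.036, against 0.0501). Counted together 7 lists were higher and 4 lower with the preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.111). The other 6 were other matrix (0.015), FAP marker (0.087), inflammatory (0.11), TGF-beta (0.079), cell cycle (-0.16) and macrophage genes (-0.16), and each lost its call without at least 1 array.

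The pA and 5'ss AMOs were compared directly because masking an intronic polyadenylation site and masking a 5' splice site can act in opposite ways on a truncated transcript. Kng2 was higher with pA AMO by 1.17 (SE 0.166, 4 arrays against 4), and Comp was at -0.98 (SE 0.207), the chemokine Cxcl13 at -0.73 (SE 0.112), the GDNF receptor Gfra1 at -0.59 (SE 0.085), the hyaluronan synthase Has2 at -0.55 (SE 0.114) and Tgfbi at -0.51 (SE 0.074). Limma passed 0 clusters (smallest adjusted p 0.266, 756 at an unadjusted p under 0.05). With the block these 6 passed, Kng2 at an adjusted p of 0.000551 and the others between 0.0347 and 0.0457. The count was 1 or 2 without each of 11 arrays and 17 without 5'ss AMO with PDGF-AA replicate 2, of which 4 are among the 6. Interferon genes were higher with pA AMO, 26 of 26 above 0 (median 0.47, adjusted p = 4.16e-30, with adjusted p = 0.251 with an estimated correlation), with Rsad2 at 1.09 (SE 0.374) and Mx1 at 0.94 (SE 0.35). Of these 19 rose adjusted over the list alone, and the median was 0.30 without pA AMO with PDGF-AA replicate 1. Most of the interferon shift was in replicate 1. There the scores without and with PDGF-AA were 0.089 and 0.807 with pA AMO, and -0.542 and -0.544 with 5'ss AMO. In replicate 2 they were -0.118 and 0.036 against -0.228 and 0.019. Cell cycle genes were higher (median 0.15, 44 of 46 above 0, adjusted p = 1.02e-19, with adjusted p = 0.321 with an estimated correlation), with the mitotic genes Kif20a at 0.37 (SE 0.083) and Prc1 at 0.39 (SE 0.127). That median was 0.089 and 0.25 without 5'ss AMO with PDGF-AA replicate 1 and replicate 2. Adipocyte genes were lower (median -0.20, 24 of 28 below 0, adjusted p = 1.35e-05, with adjusted p = 0.462 with an estimated correlation), with Adipoq at -0.96 and the adipokine Retn at -0.83. That median was -0.11 without 5'ss AMO without PDGF-AA replicate 2 and -0.13 without pA AMO with PDGF-AA replicate 1. The largest gap in the adipocyte score was in replicate 1 with PDGF-AA, at -0.376 with pA AMO and 0.554 with 5'ss AMO. The p53 list passed without the block (0.0479) and not with it (0.0841). The preset correlation gave 5 lists higher and 5 lower with pA AMO, and an estimated one 0 (smallest adjusted p 0.204). The 6 further lists were proteases (0.041), myogenic (0.20), cholesterol synthesis (-0.086), unfolded protein response (-0.048), TGF-beta (-0.056) and tendon genes (-0.13), which, like the p53 list, lost their call without at least 1 array.

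Without PDGF-AA, Kng2 differed between pA and 5'ss AMO by 1.22 (SE 0.234) and was the 1 cluster that passed with the block (adjusted p = 0.00819), while Tgfbi was at -0.50 and Sprr1a at 0.51. In limma 0 clusters passed (smallest adjusted p 1.0, 396 at an unadjusted p under 0.05), and the block count was 0 without any of the 4 arrays compared. Cholesterol synthesis genes were lower with pA AMO, 20 of 20 below 0 (median -0.25, adjusted p = 3.79e-13, with adjusted p = 0.591 with an estimated correlation), with Lss at -0.47 and Idi1 at -0.43. Interferon genes were higher, 26 of 26 above 0 (median 0.35, adjusted p = 7.81e-13, with adjusted p = 0.591 with an estimated correlation), and the median was 0.19 without 5'ss AMO without PDGF-AA replicate 1. Myogenic genes were higher (median 0.47, 21 of 22 above 0, adjusted p = 7.46e-11, with adjusted p = 0.591 with an estimated correlation), with Des at 0.83 and Myh8 at 0.81. The myogenic median was 0.22, with the call lost, without pA AMO without PDGF-AA replicate 1 and 0.28 without 5'ss AMO without PDGF-AA replicate 1. The preset correlation gave 3 lists higher and 5 lower, and an estimated one 0 (smallest adjusted p 0.591). The 5 further lists were cell cycle (0.076), myofibroblast (-0.080), glycolysis (-0.10), unfolded protein response (-0.076) and TGF-beta genes (-0.070), and each lost its call without at least 1 array.

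With PDGF-AA, Comp was lower with pA than with 5'ss AMO by -1.70 (SE 0.293), and Kng2 was higher by 1.12 (SE 0.234), with 2 arrays against 2. Both passed with the block at an adjusted p of 0.0122, among 3 clusters in all. Arxes2 was at -0.85, Galnt9 at -0.82 and Gfra1 at -0.74. Without the block 0 clusters passed in limma (smallest adjusted p 0.546, 835 at an unadjusted p under 0.05). The block count was 0 without pA AMO with PDGF-AA replicate 1, its replicate 2 and 5'ss AMO with PDGF-AA replicate 1, it was 1 without each control AMO array without PDGF-AA, and it was 31, the 3 among them, without 5'ss AMO with PDGF-AA replicate 2. Tendon genes were lower with pA AMO, 9 of 9 below 0 (median -0.22, adjusted p = 3.32e-06, with adjusted p = 0.0503 with an estimated correlation and 0.00527 by fry), with Fmod at -0.68. The tendon median was -0.35 without pA AMO with PDGF-AA replicate 2. Cell cycle genes were higher (median 0.26, 42 of 46 above 0, adjusted p = 1.07e-23, with adjusted p = 0.191 with an estimated correlation), with Kif20a at 0.62 (SE 0.118) and Prc1 at 0.65 (SE 0.179). Their median was 0.13 and 0.39 without 5'ss AMO with PDGF-AA replicate 1 and replicate 2.

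Interferon genes were also higher with pA AMO in the PDGF-AA arrays, 26 of 26 above 0 (median 0.52, adjusted p = 1.02e-24, with adjusted p = 0.191 with an estimated correlation), with Rsad2 at 1.63 (SE 0.529). This shift rests on replicate 1, where the list's score was 0.81 with pA AMO and -0.54 with 5'ss AMO, against 0.036 and 0.019 in replicate 2. The interferon median was 0.22 and 0.89 without pA AMO with PDGF-AA replicate 1 and replicate 2. Glycolysis genes were higher (median 0.22, 16 of 17 above 0, adjusted p = 1.43e-09, with adjusted p = 0.189 with an estimated correlation), with Aldoc at 0.31, and the median was 0.14 without pA AMO with PDGF-AA replicate 1. Matrix proteases were higher (median 0.094, 13 of 19 above 0, adjusted p = 0.000432, with adjusted p = 0.0678 with an estimated correlation and 0.00527 by fry). Their members moved apart, with the plasminogen activator Plau at 0.49 (SE 0.103) and the aggrecanase Adamts4 at -0.40 (SE 0.117), and the median was 0.046 without 5'ss AMO with PDGF-AA replicate 2. The complement (0.0414) and TGF-beta (0.0373) lists passed without the block, and with it their adjusted p was 0.071 and 0.0655. The preset correlation gave 6 lists higher and 5 lower in the PDGF-AA arrays, and an estimated one 0 (smallest adjusted p 0.0503). The 4 further lists were collagens (0.13), cholesterol synthesis (0.098), adipocyte (-0.27) and growth factor genes (-0.037). Of these the adipocyte list kept its call without each array in turn, as the complement and TGF-beta lists did not. The adipocyte shift still rests on replicate 1. There its score was -0.376 with pA AMO and 0.554 with 5'ss AMO, against 0.062 and 0.11 in replicate 2.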

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

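The loess and estimated-correlation tests of the glycolysis pattern, both tests of Kng2, the values within each replicate and the response genes chosen again were chosen only after the result was seen. The 27 list shifts given here are differences between the PDGF-AA effects of 2 AMOs that passed camera's test of the difference with the preset correlation. None passed with an estimated correlation. Values within replicates 1 and 2 are means over a list's members and are given as a pair.

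The glycolysis list rose with PDGF-AA with control and pA AMO, and its response with 5'ss AMO differed by -0.36 from control AMO and by 0.32 from pA AMO. Part of the difference from control AMO was a higher level with 5'ss AMO in the arrays without PDGF-AA. After cyclic loess between arrays the difference from control AMO was -0.36, so a scaling trend that loess removes does not account for it. Loess moved the median over all clusters by at most 0.02 in any comparison, but that median does not measure an intensity-dependent trend. Between the replicates loess lowered the clusters that differed from 7013 to 2603. How much of a trend it removed in this comparison was not measured. Members moving together by chance in a few cultures stays open, since the adjusted p with an estimated correlation was 0.151. A wider change of hypoxia-inducible genes is a candidate explanation: 18 such genes outside all 24 lists had a median change of 0.336 over control and pA AMO. Cell density and oxygen supply differing between cultures were not tested.

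Kng2 was lower in all 4 arrays with 5'ss AMO than in the other 8. After cyclic loess the change of Kng2 was -1.28, so a scaling trend that loess removes does not account for it. The arrays were already quantile-normalized, and loess moved the median over all clusters by at most 0.02 in any comparison. That median does not measure an intensity-dependent trend, and how much of one loess removed in this comparison was not measured. Signal of the similar paralog Kng1 stays open. The Kng1 cluster differed by 0.085 between 5'ss and control AMO (SE 0.134), by -0.29 without and 0.46 with PDGF-AA (SE 0.19 each), and which paralog the probes of either cluster detect was not tested. An effect of the 5'ss oligonucleotide on transcripts other than Pdgfra and an effect through Pdgfra both stay open and were not tested.

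Arrays of replicates 1 and 2 differed at 7013 clusters, of which 3336 were higher and 3677 lower in replicate 2, and the first principal component held 39.1% of the variance. After cyclic loess 2603 clusters still differed, so intensity-dependent scaling may account for a part. Another cell type in the cultures of a replicate stays open as well: myogenic genes had a median of -0.278 between replicates 2 and 1, with 1 of 22 above 0. Neither test decides. Each biological replicate pools cells of 2 mice, so a difference between pools stays open, and no label says which arrays share a pool, a batch or a day. The study's design names no difference between the replicates, and no difference between the animals was tested.

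The count of genes in each averaged comparison was set against other splits of the same arrays in a 2-group fit. For PDGF-AA the real split gave 0 clusters and all 100 of 100 splits drawn from 462 gave as many, with 532 as the highest of the others. For pA against control AMO 35 of 35 splits gave as many as the real 0, with a highest of 1363. For 5'ss against control AMO 2 of 35 gave as many as the real 1, with a highest of 970, and for pA against 5'ss AMO 35 of 35 gave as many as the real 0, with a highest of 3962. A real count of 0 is reached by every split, so in 3 of these fits the splits decide nothing. For 5'ss against control AMO the other split with as many is the one by replicate number, so this fit, which leaves out the pairing, does not exclude chance, and the count with the block is 3. The split by replicate number gave 6566 clusters for the 12 arrays and the highest count in each of the other 3, which points to a structure of the samples.

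With the block and labels swapped within pairs, 1 of 32 splits, the real split itself, gave 21 clusters for PDGF-AA. The highest of the others was 15. The real split thus had the highest count, and 32 splits can give no smaller share. This count does not exclude chance, since the pairing it rests on is a hint from the data and not from the labels. With all clusters tested, unnamed ones included, the PDGF-AA count with the block was 0. For the AMO comparisons the 8 swaps are too few for a share under 0.05. The real values were 0, 3 and 6 for pA against control, 5'ss against control and pA against 5'ss AMO, as many came from 8, 1 and 1 of the swaps, and the highest of the others was 0 in each.

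The response of the 100 genes chosen with control AMO differed between pA and 5'ss AMO by 0.226. It was 0.29 with genes chosen above the dim threshold, 0.18 chosen with the block and 0.27 chosen with both, which passed by fry before adjustment. It was 0.072 for 500 genes, and 0.036 to 0.12 when the 100 genes were chosen again without a single control AMO array, and none of these passed.

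For pA minus control AMO, the PDGF-AA effect differed by 0.378 for interferon, -0.366 for myogenic, -0.174 for macrophage and 0.082 for other matrix genes. Within replicates 1 and 2 the differences were 0.52 and 0.44 for interferon, -0.25 and -0.51 for myogenic, -0.27 and -0.031 for macrophage and 0.19 and 0.018 for other matrix genes. Each of these 4 calls was lost without at least 1 array, and with the dim filter the macrophage value was -0.018. The interferon median was 0.17 without control AMO with PDGF-AA replicate 2 and 0.0090 without pA AMO with PDGF-AA replicate 1, where its call was lost.

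For 5'ss minus control AMO, besides glycolysis (-0.357), the PDGF-AA effect differed by 0.317 for tendon, 0.315 for complement, 0.22 for adipocyte, -0.265 for cholesterol, -0.187 for macrophage, -0.148 for cell cycle, -0.146 for collagen, 0.106 for interferon, 0.101 for inflammatory and 0.047 for growth factor genes. Replicate 2 showed little or none of several differences seen in replicate 1. The pairs were 1.02 and -0.030 for adipocyte, -0.47 and -0.054 for cholesterol, -0.19 and -0.049 for macrophage, -0.21 and -0.036 for collagen, and 0.40 and 0.12 for complement genes. For interferon genes the values had opposite signs, at -0.20 and 0.53, and only replicate 2 had the sign of the called shift. The other pairs were -0.28 and -0.40 for glycolysis, 0.32 and 0.57 for tendon, -0.16 and -0.15 for cell cycle, 0.12 and 0.29 for inflammatory and 0.15 and 0.12 for growth factor genes. The glycolysis, tendon and complement calls held without each array in turn, and the other 8 did not. With the dim filter the macrophage value was 0.075. With the block the adjusted p of the interferon list was 0.0814, against 0.0275 without it.

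For pA minus 5'ss AMO, besides glycolysis (0.321), the PDGF-AA effect differed by -0.616 for myogenic, 0.368 for cholesterol, -0.236 for adipocyte, 0.218 for cell cycle, 0.209 for interferon, 0.188 for collagen, -0.176 for tendon, -0.174 for complement, 0.12 for protease, 0.059 for unfolded protein response and -0.051 for inflammatory genes. Several were near 0 in replicate 2. The pairs for replicates 1 and 2 were -1.02 and -0.0050 for myogenic, -0.98 and 0.031 for adipocyte, 0.42 and 0.0040 for cell cycle, 0.30 and 0.0080 for collagen, 0.61 and 0.070 for cholesterol, and 0.72 and -0.094 for interferon genes. They were 0.37 and 0.22 for glycolysis, -0.42 and -0.46 for tendon, 0.13 and 0.10 for protease, -0.30 and -0.10 for complement, 0.075 and 0.058 for unfolded protein response and -0.017 and -0.17 for inflammatory genes. The calls of glycolysis, tendon, cell cycle, collagen, cholesterol and myogenic genes held without each array in turn, and the other 6 did not. With the block the adjusted p of the unfolded protein response list was 0.0588, against 0.0433 without it.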

How the results depend on the processing

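Cyclic loess, the scaling and dim-cluster alternatives for list shifts, every alternative for counts with the replicate block, and the reselection of response genes were chosen after the results were seen. Genes named in the report kept their sign under every setting run, except Pdgfra, and Pdgfb, Actc1 and Myh3 when single arrays were left out. No result here has more than 2 arrays per group, and signal near background limits dim clusters such as Mrgpra6.

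With trend and robust moderation limma gave 39 clusters for averaged PDGF-AA, 13 for PDGF-AA with control AMO, and 7 and 6 for 5'ss against control AMO, averaged and with PDGF-AA, and 2 for pA against 5'ss AMO averaged. With the replicate block and no other change the counts were 21 for averaged PDGF-AA, 3, 1 and 22 for 5'ss against control AMO averaged, without and with PDGF-AA, and 6, 1 and 3 for pA against 5'ss AMO in the same order. For 5'ss against control AMO with PDGF-AA the unblocked count was 1 among clusters above the dim threshold and 3 after repeated quantile normalization. Of the calls with the block, the same 19 of the averaged PDGF-AA calls were among the 65 with the dim filter. The block changed the calls of 12 list shifts, 11 of them given in the comparisons or among the differences of PDGF-AA effects. The other was FAP markers, brought past the threshold for 5'ss minus control AMO (adjusted p 0.0241 against 0.0551). It changed 9 fry calls. Those lost were tendon for averaged PDGF-AA (adjusted p 0.0385, and 0.0644 with the block), tendon and protease genes for pA against 5'ss AMO averaged (0.048 and 0.0474, both 0.0933) and for pA minus 5'ss (both 0.0438, then 0.0566), and tendon and glycolysis genes for 5'ss minus control (both 0.0375, then 0.0601). Those gained were growth factors with control AMO (0.0855, then 0.0309) and pA AMO (0.103, then 0.0355).

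Counts with the block moved with other choices. With trend and robust moderation they were 228 for averaged PDGF-AA, 203 and 414 for 5'ss against control AMO averaged and with PDGF-AA, and 158, 12 and 160 for pA against 5'ss AMO averaged, without and with PDGF-AA. With the dim filter, which tests fewer clusters, they were 65, 20, 68 and 12 for averaged PDGF-AA, 5'ss against control AMO averaged and with PDGF-AA, and pA against 5'ss AMO averaged. With all 35556 clusters tested they were 0 for averaged PDGF-AA, 1, 0 and 0 for 5'ss against control AMO averaged, without and with PDGF-AA, and 1, 0 and 0 for pA against 5'ss AMO in the same order. Repeated quantile normalization gave 1 for both averaged AMO comparisons, and cyclic loess gave 7 for 5'ss against control AMO and 1 for pA against 5'ss AMO. The cause was not tested.

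Leaving out single arrays gave unblocked counts of 0 to 1 for 5'ss against control AMO, averaged and with PDGF-AA. Counts with the block were 0 to 24 for averaged PDGF-AA, 1 to 10, 0 to 1 and 0 to 21 for 5'ss against control AMO averaged, without and with PDGF-AA, and 1 to 17, 0 to 1 and 0 to 31 for pA against 5'ss AMO. A lone array was taken to vary like the other groups.

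With an estimated correlation 0 lists passed in each of the 16 comparisons. Fry called 3 for averaged PDGF-AA, 2, 3 and 0 for control, pA and 5'ss AMO, 0 for each pA against control comparison, 0, 0 and 1 for 5'ss against control AMO, 2, 0 and 2 for pA against 5'ss AMO, and 0, 2 and 2 for the differences pA minus control, 5'ss minus control and pA minus 5'ss. Camera's preset counts fell with scaling in 4 comparisons. For pA against control AMO averaged, 7 lists became 3 after quantile normalization, loess, and loess with the block. With PDGF-AA, 6 became 2, 1 and 1, for 5'ss against control AMO averaged 11 became 4, 5 and 4, and for pA minus control 4 became 2 in each.

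Without single arrays the number of lists called ran from 6 to 12 for averaged PDGF-AA, 1 to 11 with 5'ss AMO, 4 to 13, 1 to 6 and 4 to 12 for pA against control AMO averaged, without and with PDGF-AA, 5 to 11 and 4 to 10 for 5'ss against control AMO averaged and without PDGF-AA, and 5 to 12 for pA against 5'ss AMO averaged. For the differences pA minus control, 5'ss minus control and pA minus 5'ss it ran from 1 to 11, 6 to 13 and 7 to 15.

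Changes of Pdgfra near 0 turned sign. For averaged PDGF-AA (-0.0050) the value was 0.013 after quantile normalization and 0.0010 after median centring. For pA against control AMO averaged it was 0 after quantile normalization and -0.010 after loess with the block, without PDGF-AA -0.0040 after median centring and -0.0060 after loess with the block, with PDGF-AA -0.013 and -0.015 after quantile normalization and loess with the block, and for pA minus control 0.017 after median centring. Without single arrays Pdgfra ran from -0.019 to 0.0090 for averaged PDGF-AA, -0.026 to 0.056 with pA AMO, -0.010 to 0.031, -0.029 to 0.053 and -0.023 to 0.041 for pA against control AMO averaged, without and with PDGF-AA, and -0.044 to 0.038 for pA minus control. Pdgfb ran from -0.041 to 0.090 for averaged PDGF-AA. Actc1 ran from -0.017 to 1.34 and Myh3 from -0.17 to 1.45 for pA against control AMO without PDGF-AA.

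Some list shifts turned direction in camera. Camera's direction need not follow the sign of the median, so some of the medians below stay on 1 side of 0. With the dim filter, which removes members, macrophage genes were at -0.0020 for 5'ss against control AMO with PDGF-AA, -0.018 for pA minus control and 0.075 for 5'ss minus control. Without single arrays, medians with 5'ss AMO ran from -0.26 to 0.033 for cell cycle, -0.29 to 0.047 for cholesterol and -0.0070 to 0.36 for myogenic genes. For pA against control AMO they ran from -0.055 to 0.19 for cell cycle without PDGF-AA, and with PDGF-AA from -0.14 to 0.51 for interferon and -0.26 to -0.031 for macrophage genes. For 5'ss against control AMO, cell cycle ran from -0.14 to -0.0090 averaged and -0.28 to -0.027 with PDGF-AA. For pA against 5'ss AMO, cholesterol ran from -0.15 to -0.0010 averaged and -0.039 to 0.25 with PDGF-AA, and TGF-beta targets from -0.19 to 0.033 with PDGF-AA. For 5'ss minus control, cell cycle ran from -0.30 to -0.016 and interferon from -0.11 to 0.36, and for pA minus 5'ss interferon ran from -0.048 to 0.51. The response difference of 0.23 was 0.072 with 500 genes and ran from 0.036 to 0.26 without single arrays.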

Other observations

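The hypoxia-inducible list was written after Car9, Egln3 and Slc16a3 had been seen among the PDGF-AA genes, and these 3 were left out of it, while its prediction was written before its values were seen. The list holds 18 genes and shares none with the 24 fixed lists. Averaged over control and pA AMO, 17 of the 18 genes were higher with PDGF-AA (median 0.34). Adjusted over 5 contrasts of this list, fry in limma gave an adjusted p of 0.00331 and camera with an estimated correlation an adjusted p of 0.0208 (0.0056 before adjustment). The adjusted p of this list, here and below, are not adjusted over the 24 fixed lists. They cannot be set beside the adjusted p of those lists. The median was 0.32 with control AMO and 0.28 with pA AMO, each with an adjusted p of 0.00818 by fry. The mitophagy gene Bnip3 was at 0.51 and 0.52 in these, Higd1a at 0.42 and 0.63, Fam162a at 0.54 and 0.41, and the adenylate kinase Ak4 at 0.46 and 0.48. With 5'ss AMO the median was 0.043, with 12 of 18 above 0 (adjusted p = 0.662), and Bnip3 was at 0.040.

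The change with 5'ss AMO minus the mean of the other AMOs was -0.26 for this list, with 1 of 18 genes above 0 (adjusted p = 0.0234 by fry in limma and 0.0367 by camera with an estimated correlation). By unadjusted fry it no longer passed without 5'ss AMO without PDGF-AA replicate 2 (-0.21) and without 5'ss AMO with PDGF-AA replicate 1 (-0.27). A hypothesis is that PDGF-AA may have raised a hypoxia-type program in cultures with control and pA AMO. Their median of 0.336 met the prediction set for it. The list was written after Car9, Egln3 and Slc16a3 had been seen in these same arrays, so meeting the prediction is not independent support. That prediction did not cover 5'ss AMO. Differences in oxygen or cell density between wells were not measured and stay open.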
